A study of Homo sapiens with 8 samples.

How the data were processed

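DNA recovered with each of 3 biotinylated RNA oligos, or with no oligo, was sequenced from 2 libraries per group, 8 libraries in 4 groups. Per the labels' protocols, 6 to 7 µg of RNA-free H1 DNA sonicated to 200 to 300 bp was mixed with 20 pmol of oligo for 1 h at 37 °C in 50 mM KCl and 5 mM MgCl2, bound to streptavidin beads, and released with RNases, in independent experiments for the pair of libraries. Per the submitters' processing notes, FastQC and BWA 0.7.15-r1140 were used and the genome build was hg38. The program that called the regions, its settings and the scaling of the libraries are not given in the sources used here. The input named in the design text was not analysed here.

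The 6 deposited lists give each region's position, gene names chosen by the authors and one log2 ratio per region, positive in captured and negative in control lists. That the authors' values are on a log2 scale was read from the values: 2 to the power of the value was a ratio of whole numbers with a denominator of at most 400, within 3e-10, for 98.2% to 99.96% of the regions of a list, and e to the power of it for at most 0.0086%. What the whole numbers count is unknown, as is the error of a ratio. A value of 2.5 that goes with the names of the lists is not explained and was not used. The lists hold no p-value and no value per library, so depth, the agreement of the libraries and any fit that leaves a library out could not be computed. Regions were 150 bp wide or more. The lists were used as deposited, 327994 regions on 23 chromosomes, with coordinates printed from 1.

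Genes came from a RefSeq table of GRCh38.p14 with 59094 genes, 19970 of them protein-coding, which gives gene ends but no strand, exon or transcription start. No genome sequence was used here. The planned promoter class was therefore replaced by the gene edge, within 1 kb of either end of a protein-coding gene, and exon, intron and intergenic DNA by 3 other classes of region midpoints: inside a protein-coding gene, inside another gene, and between genes. A region at the gene edge can thus lie at the transcription start or at the far end. The planned purine tract, 6-mer and GC comparisons were not made, and nothing below bears on triplex sequence. Of the authors' gene names, 69.8% matched the table, and names were taken from the table.

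Overlap was at least 1 bp. Chance came from 1000 placements of each region on its own chromosome, within the 2722 Mb called span of the 22 autosomes, leaving out stretches over 1 Mb empty in all lists. The 162 regions on X were left out of placements, overlap and classes. The 848 protein-coding genes of X stayed in the Fisher's exact tests of gene lists and families, although few captured regions lie there. That somewhat raises the odds ratios of autosomal lists. Gene counts against moved regions used autosomal genes only. Overlap used a one-sided placement p and classes a two-sided one. Classes and gene lists were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 12 and 36 tests and a threshold of 0.05, and odds ratios between oligos by the difference of their logarithms. That difference treats the odds ratios as independent, although the comparisons share the no-oligo libraries. The 12 gene lists were written before the files were opened, all of their genes were in the table, and each is reported except 1, which is not described here and passed the threshold with no oligo. The genes named were, for each oligo, the 10 protein-coding genes whose edge region had the highest log2 ratio, up to 4 from each list, the 3 highest regions anywhere, and MEG3, DLK1, GATA6-AS1 and GATA6. The text gives a part of those taken from the lists. The rule asked for the smallest p, which the lists do not give, so the log2 ratio took its place.

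Alternatives planned in advance were the 50% of regions with the largest log2 ratio in size, joining regions within 200 bp, overlap of at least 0.5 of the shorter region, edges of 5 kb, and gene bodies with 5 kb to each side. Keeping chromosomes 1 to 22 and X only was also planned and removed no region. Added after seeing the data were a log2 ratio of at least 1.5 in size, leaving out chromosome 1, strata of region density within 500 kb of a gene, and regions moved by 20 kb to 200 kb. For gene lists the moved count was also set against all other genes, using 10000 random gene lists, after the plain ratio had been seen to exceed 1 for most lists with GATA6-AS TFR1: over all autosomal protein-coding genes that ratio was 1.65 for GATA6-AS TFR1, 1.25 for MEG3 TFR1 and 1.22 for MEG3 TFR2. Tests of 14 gene families defined by symbol were also added later. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

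The methods were tested on simulated lists made from the MEG3 TFR2 captured list (73515 regions). Independent placement gave an overlap of 0.992 times chance and a gene edge share of 1.03 times chance. A planted overlap of 22.3% was recovered as 22.2%. Of 100 random gene lists of 40 genes, 1% had p under 0.05 by Fisher's exact test and 5% by the random-list test. Those genes were drawn at random and do not lie in clusters, as HOX genes do. The shared no-oligo libraries were not simulated either. The checks therefore do not cover clustered genes or the shared control.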

Results

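Sonicated, RNA-free genomic DNA of H1 cells, a human embryonic stem cell line, was incubated with biotinylated RNA oligos and the DNA that stayed with the RNA was recovered on streptavidin beads and sequenced. The 3 oligos carry sequences of long noncoding RNAs: MEG3 TFR1 and MEG3 TFR2 come from MEG3, a maternally expressed RNA of the imprinted DLK1-DIO3 domain, and GATA6-AS TFR1 comes from the transcript antisense to GATA6, which encodes an endoderm and heart transcription factor. TFR is read here as a region able to form an RNA-DNA triplex, in which the RNA lies in the major groove of the DNA duplex. Each of the 3 oligos and the no-oligo control had 2 libraries, 8 in all. The data are 6 lists of genomic regions on hg38, for each oligo one list of regions with more signal with the oligo (captured) and one with more signal without it (control). No expression was measured, so genes are named below only for where captured DNA lies. The lists carry no value per library and no read total, so the spread between the 2 libraries of a group and the depth are unknown. Every p-value below is over regions, genes or autosomes, which are not replicates, and describes these lists alone.

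The first comparison asks how much DNA each oligo recovered beyond the beads alone. GATA6-AS TFR1 had the longest captured list, with 104786 regions covering 49.5 Mb, followed by MEG3 TFR1 with 89739 regions covering 38.0 Mb and MEG3 TFR2 with 73546 regions covering 26.7 Mb. The control lists held 36330, 12649 and 10944 regions in the same order. There were therefore 2.88 captured regions per control region for GATA6-AS TFR1, against 7.09 for MEG3 TFR1 and 6.72 for MEG3 TFR2. Captured regions had a median width of 400 bp for GATA6-AS TFR1 and 350 bp for both MEG3 oligos. Their median log2 ratio over the no-oligo control, the authors' value for each region, was 1.34 for GATA6-AS TFR1, 1.41 for MEG3 TFR1 and 1.44 for MEG3 TFR2. The largest ratios belonged to narrow regions: width and log2 ratio correlated across captured regions with a Spearman rho of -0.50 for MEG3 TFR1, -0.42 for MEG3 TFR2 and -0.37 for GATA6-AS TFR1, regions not being independent replicates. Among regions with a log2 ratio of at least 1.5 in size, captured regions per control region fell to 1.83 for GATA6-AS TFR1 and were 5.69 and 6.45 for MEG3 TFR1 and MEG3 TFR2. No test was made, since each comparison has one list per direction.

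**Figure D1:**
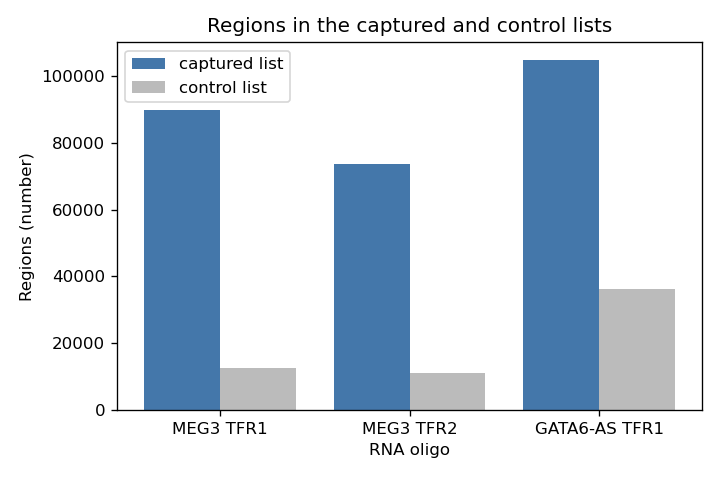
Number of regions (y axis) in the captured (blue) and control (grey) list of each RNA oligo (x axis). The captured lists hold 89739, 73546 and 104786 regions and the control lists 12649, 10944 and 36330.

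Captured regions followed the gene-rich chromosomes. Chromosome 19 held 95.1 captured regions per Mb for MEG3 TFR1, 67.8 for MEG3 TFR2 and 150 for GATA6-AS TFR1, the highest density of the 22 autosomes for each oligo. Chromosome 4 was the least dense for both MEG3 oligos, and chromosome 18 for GATA6-AS TFR1, at 16.6 per Mb. On chromosome 1 there were 15.9 captured regions per control region for MEG3 TFR1 and 11.95 for MEG3 TFR2, above the highest of the other 21 autosomes (12.2 and 9.54, both on chromosome 19). For GATA6-AS TFR1 the chromosome 1 value was 4.91, below the 7.29 of chromosome 19. Chromosome 21 had the fewest captured regions per control region for MEG3 TFR1, 2.33, and for MEG3 TFR2, 2.20. Chromosome X held 158 of the 268071 captured regions and was left out of the placements.

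The second comparison asks whether the oligos recovered the same loci. Most captured regions were listed for a single oligo: 72.6% of the MEG3 TFR1, 64.4% of the MEG3 TFR2 and 71.9% of the GATA6-AS TFR1 regions overlapped neither other list. Of 221540 loci formed by merging the captured lists, 184936 (83.5%) held regions of 1 oligo, 30246 (13.7%) of 2 and 6358 (2.87%) of all 3, a count in which shared regions merge into one locus. Of the MEG3 TFR2 regions, 17.6% overlapped a MEG3 TFR1 region and 25.1% a GATA6-AS TFR1 region, and 19.0% of the MEG3 TFR1 regions overlapped a GATA6-AS TFR1 region. Placing the regions at random on the same chromosomes gave 2.86%, 3.76% and 4.19%, so the observed shares were 6.13, 6.67 and 4.53 times chance. Each had a one-sided placement p of 0.001, the smallest that 1000 placements can give. The 95% Wilson intervals of the shares were 17.3% to 17.8%, 24.8% to 25.4% and 18.7% to 19.3%. When each region was moved by only 20 kb to 200 kb, which keeps the regional density and was chosen after seeing the data, the shares were 3.46, 3.51 and 2.37 times chance. Whether the pairs differ from each other in overlap was not tested, and the GATA6-AS TFR1 list is the longest.

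The control lists overlapped far more than the captured lists. Of the shorter control list, 54.4% overlapped between MEG3 TFR1 and MEG3 TFR2, 76.1% between MEG3 TFR1 and GATA6-AS TFR1 and 80.9% between MEG3 TFR2 and GATA6-AS TFR1, at chance values of 0.323%, 0.851% and 0.844%. Captured regions of one oligo overlapped control regions of another less often than chance, at 0.325 to 0.592 times the placed value over the 6 combinations. All comparisons use the same no-oligo libraries, and without values per library unchanged groups could not be simulated, so part of the overlap of the captured lists over chance may come from the shared control.

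**Figure D2:**
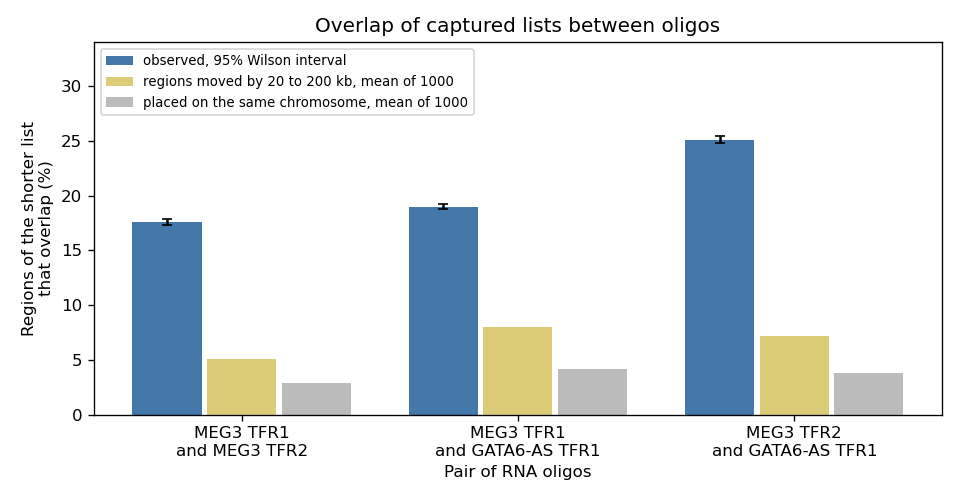
Share of the regions of the shorter captured list that overlap the other list (y axis, percent) for the 3 pairs of oligos (x axis), observed with 95% Wilson intervals (blue), after moving each region by 20 kb to 200 kb (yellow) and after placing it anywhere on its chromosome (grey), means of 1000. Observed shares of 17.6%, 19.0% and 25.1% lie above both.

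The third comparison asks where captured DNA lies relative to genes. Regions of all 3 oligos lay more often at the edges of protein-coding genes, within 1 kb of either end, than the control regions did. The share was highest for GATA6-AS TFR1, at 10.9% of captured against 2.66% of control midpoints (odds ratio 4.48, 95% interval 4.19 to 4.79). It was 5.99% against 2.91% for MEG3 TFR1 (odds ratio 2.13, 1.91 to 2.37; adjusted p 5.08e-52) and 5.54% against 3.26% for MEG3 TFR2 (odds ratio 1.74, 1.56 to 1.94; adjusted p 7.55e-26, two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 12 tests). The odds ratio of GATA6-AS TFR1 was larger than that of either MEG3 oligo: the ratio of odds ratios was 0.474 for MEG3 TFR1 over GATA6-AS TFR1 (adjusted p 3.74e-30) and 0.388 for MEG3 TFR2 over GATA6-AS TFR1 (adjusted p 5.92e-46). Against placements on the same chromosome, the captured share at gene edges was 3.35 times chance for GATA6-AS TFR1, 1.95 times for MEG3 TFR1 and 1.87 times for MEG3 TFR2. Against captured regions moved by 20 kb to 200 kb it was 1.97, 1.30 and 1.26 times chance (two-sided permutation p = 0.002 each over 1000 moved lists, the smallest possible). DNA between genes was the less captured part, with odds ratios of 0.658 for GATA6-AS TFR1, 0.795 for MEG3 TFR1 and 0.806 for MEG3 TFR2. Against moved regions its ratio was 0.888 for GATA6-AS TFR1 and 0.972 for MEG3 TFR2, and 1.00 for MEG3 TFR1 (two-sided permutation p = 0.380), which ended the call for that oligo. The insides of protein-coding genes had odds ratios of 1.15 for GATA6-AS TFR1, 1.12 for MEG3 TFR1 and 1.14 for MEG3 TFR2. Against the moved regions the ratios were 0.978 for GATA6-AS TFR1 and 0.967 for MEG3 TFR1 (two-sided permutation p = 0.002 each). For MEG3 TFR2 the ratio was 0.996 (two-sided permutation p = 0.148). Midpoints at edges are not counted as inside, so an excess at edges lowers the share inside.

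**Figure D3:**
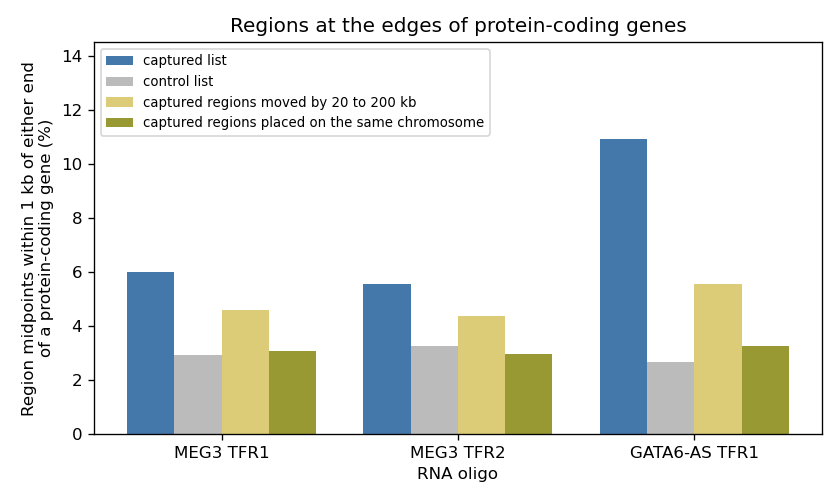
Share of region midpoints within 1 kb of either end of a protein-coding gene (y axis, percent) for each oligo (x axis), in the captured list (blue), the control list (grey), and for captured regions moved by 20 kb to 200 kb (yellow) or placed on the same chromosome (olive), means of 1000. The captured shares are 5.99%, 5.54% and 10.9%.

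Counted by gene, 9355 of 19970 protein-coding genes (46.8%) had a GATA6-AS TFR1 region within 1 kb of either end, 5625 (28.2%) a MEG3 TFR1 region and 4439 (22.2%) a MEG3 TFR2 region. All 3 oligos had a region at 1928 genes (9.65%), and 8204 genes (41.1%) had none. Control regions lay at 1182, 466 and 444 genes in the same order.

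The fourth comparison asks which gene groups lie at captured DNA, over 12 lists fixed before the data were examined. HOX genes, which pattern the body axis, had captured regions at their edges more often than other genes with all 3 oligos: 36 of 39 with GATA6-AS TFR1 (odds ratio 13.7, 95% interval 4.21 to 44.4; adjusted p 9.62e-08), 28 with MEG3 TFR1 (odds ratio 6.52, 3.24 to 13.1; adjusted p 3.51e-07) and 19 with MEG3 TFR2 (odds ratio 3.33, 1.78 to 6.25; adjusted p 0.0035, Fisher's exact tests over 36 tests). All 9 HOXC genes had a region with MEG3 TFR1 and with GATA6-AS TFR1, and 6 had one with MEG3 TFR2, whereas 1 of 11 HOXA genes had one with MEG3 TFR2. The highest HOX ratio of each oligo was at HOXC11 (6.94-fold with MEG3 TFR2), HOXB8 (6.13-fold with MEG3 TFR1) and HOXC8 (4.46-fold with GATA6-AS TFR1). Whether the HOX excess goes beyond its surroundings was left open by 2 controls, both chosen after seeing the data. Within strata of region density within 500 kb it passed with all 3 oligos (odds ratio 11.6 for GATA6-AS TFR1, adjusted p 8.56e-05; 8.31 for MEG3 TFR1, adjusted p 3.68e-06; 2.85 for MEG3 TFR2, adjusted p 0.0241; Cochran-Mantel-Haenszel tests over genes). Set against regions moved by 20 kb to 200 kb and against all other genes, the HOX ratio was 1.46 for MEG3 TFR1, 1.31 for MEG3 TFR2 and 1.17 for GATA6-AS TFR1, and none passed (adjusted p = 0.356, 0.540 and 0.540 by permutation over random gene lists). HOX genes lie in 4 clusters of 103 to 200 kb and share regions, so they are not independent, and moved regions often stay inside a cluster. Counted over the whole gene with 5 kb to each side, HOX missed the threshold with MEG3 TFR2 (odds ratio 3.24, adjusted p 0.0550, Fisher's exact test).

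No other list passed the planned test at gene edges with any oligo. Cardiac genes came nearest, with a region at 17 of 24 for GATA6-AS TFR1 (odds ratio 2.76, adjusted p 0.167), 12 for MEG3 TFR1 (odds ratio 2.55, adjusted p 0.167) and 7 for MEG3 TFR2 (odds ratio 1.44). They include the myosin genes MYH6 (4.19-fold with MEG3 TFR1, 4.07-fold with MEG3 TFR2) and MYL7 (4.37-fold and 4.88-fold) and the transcription factor gene HAND2 (4.35-fold with GATA6-AS TFR1). Neuroectoderm genes had a region at 16 of 24 with GATA6-AS TFR1 (odds ratio 2.27, adjusted p 0.388), among them PAX6 at 4.71-fold, and at 10 and 3 with MEG3 TFR1 and MEG3 TFR2 (odds ratios 1.82 and 0.499). Within strata of region density, neuroectoderm genes passed with GATA6-AS TFR1 (odds ratio 3.87, adjusted p 0.0241). Against moved regions and other genes they did not (ratio 1.84, adjusted p 0.0576 by permutation over random gene lists). Both controls were chosen after seeing the data. Endoderm and mesoderm genes had one at 14 of 25, 10 and 4 for GATA6-AS TFR1, MEG3 TFR1 and MEG3 TFR2 (odds ratios 1.44, 1.70 and 0.666), with TBXT, the brachyury gene, at 7.50-fold and 8.56-fold for the first and the second. Pluripotency genes had one at 14 of 26, 8 and 6 (odds ratios 1.32, 1.13 and 1.05), including OTX2 at 7.50-fold with GATA6-AS TFR1 and POU5F1 at 4.36-fold and SOX2 at 2.72-fold with MEG3 TFR2.

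TGF-beta and BMP signalling genes, which have been linked to MEG3, had a region at 22 of 46 with GATA6-AS TFR1, 14 with MEG3 TFR1 and 8 with MEG3 TFR2 (odds ratios 1.04, 1.12 and 0.736). Among them THBS1, an activator of latent TGF-beta, stood at a log2 ratio of 3.46 with GATA6-AS TFR1 and at 4.82-fold with MEG3 TFR1, and the ligand gene TGFB3 at 2.90-fold with MEG3 TFR1 and 4.82-fold with MEG3 TFR2. Endothelial genes had a region at 17 of 32, 11 and 8 (odds ratios 1.29, 1.34 and 1.17), with the ephrin receptor gene EPHB4 at 4.75-fold with MEG3 TFR1 and 5.86-fold with MEG3 TFR2 and ROBO4 at 7.14-fold with GATA6-AS TFR1. Genes of Polycomb components, the repressive chromatin complexes, had one at 15 of 30, 9 and 9 (odds ratios 1.13, 1.09 and 1.5), with PHF1 at 12.4-fold with GATA6-AS TFR1 and MTF2 at 5.44-fold, 5.38-fold and 5.08-fold for GATA6-AS TFR1, MEG3 TFR1 and MEG3 TFR2. Imprinted genes had one at 18 of 30, 5 and 7 (odds ratios 1.70, 0.510 and 1.06), including DIO3 at 6.44-fold with GATA6-AS TFR1 and IGF2 at 3.14-fold and 3.83-fold with the MEG3 oligos.

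Genes of synaptic adhesion and ion channels had a region at 14 of 30, 12 and 9 for GATA6-AS TFR1, MEG3 TFR1 and MEG3 TFR2 (odds ratios 0.993, 1.70 and 1.5), with the glutamate receptor gene GRIN2A at 9.50-fold with GATA6-AS TFR1 and 5.85-fold with MEG3 TFR2. Counted over the whole gene with 5 kb to each side, this list passed with all 3 oligos (odds ratios 9.04, 5.73 and 6.68; adjusted p = 0.0331, 0.0331 and 0.0170, Fisher's exact tests), and gene length was not matched in that count. At gene edges they passed with MEG3 TFR1 within strata of region density (odds ratio 3.09, adjusted p 0.0446) and against moved regions and other genes (ratio 1.97, adjusted p 0.0360 by permutation), both chosen after seeing the data, and with neither other oligo. Ribosomal protein genes, taken as a comparison list, had a region at 39 of 70, 19 and 20 (odds ratios 1.43, 0.950 and 1.40), and passed for GATA6-AS TFR1 when edges were widened to 5 kb (odds ratio 2.48, adjusted p 0.0206).

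**Figure D4:**
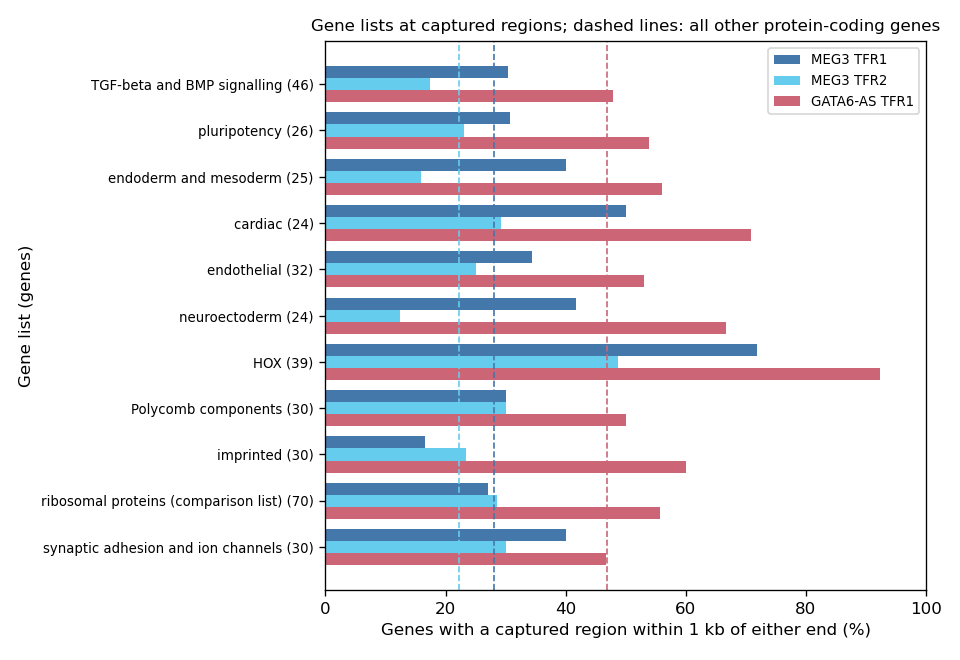
Share of the genes of each list with a captured region within 1 kb of either end (x axis, percent) for the lists described here (y axis, number of genes in brackets) and the 3 oligos (colours), with all other protein-coding genes as dashed lines. HOX genes stand at 71.8%, 48.7% and 92.3% against 28.1%, 22.2% and 46.8% of other genes.

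The highest ratios at gene edges were spread over different genes for each oligo. With MEG3 TFR1 they were at AHDC1 (chromosome 1, 27603801 to 27604050, inside the gene, 56.0-fold), KLF6 (chromosome 10, 3786051 to 3786250, beside the gene, 30.7-fold), which encodes a zinc finger transcription factor, and EML2 (chromosome 19, 45644751 to 45644950, 23.8-fold), followed by NDNF, CDC42EP1, LOC124901498, SCNN1G, CACNB3, TNFRSF13B and TNXB at 14.6-fold to 19.8-fold. With MEG3 TFR2 they were at METTL13 (chromosome 1, 171782451 to 171782700, inside the gene, 20.5-fold), MGAT5B (chromosome 17, 76869351 to 76869550, 17.6-fold) and VWA5B1 (chromosome 1, 20291251 to 20291750, 16.6-fold), followed by NPTXR, EPOP, GRIK4, TNXB, CUZD1, RNASEH2C and MFSD12 at 13.9-fold to 16.5-fold. With GATA6-AS TFR1 they were at ADNP2 (chromosome 18, 80108301 to 80108500, beside the gene, 30.3-fold), ARHGAP33 (chromosome 19, 35775851 to 35776200, 25.5-fold) and SLC22A23 (chromosome 6, 3455501 to 3456150, 24.8-fold), followed by ELFN2, SLCO5A1, COL27A1, HTR6, LOC124903972 and LRRC37B, which share a region, and COTL1 at 18.0-fold to 24.7-fold. TNXB, the tenascin X gene, was named for both MEG3 oligos by the same region (chromosome 6, 32109751 to 32110100), at 14.6-fold and 14.7-fold. Anywhere in the genome, the highest ratio was 76.0-fold with MEG3 TFR2 inside CARMIL1 (chromosome 6, 25502201 to 25502500). The next 2 with that oligo lay outside genes (chromosome 9, 115843751 to 115844000, 61.5-fold; chromosome 4, 103942551 to 103942850, 47.0-fold). For MEG3 TFR1, after AHDC1, they lay in the immunoglobulin heavy chain locus (chromosome 14, 105738101 to 105738350, 56.0-fold) and outside genes (chromosome 10, 42933201 to 42933400, 48.5-fold). For GATA6-AS TFR1 they lay in TMEM191A (chromosome 22, 20702801 to 20703050, 57.5-fold), in LINC01854 (chromosome 2, 129255501 to 129255700, 52.5-fold) and in LRRC9 (chromosome 14, 60012951 to 60013250, 49.0-fold). The 9 highest ratios were all multiples of 0.5, as whole-number ratios with a denominator of 1 or 2 are, so their sizes are uncertain and depend on the no-oligo value. These ranks hold within each list, since lists of different length are not comparable by rank.

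The last comparison asks whether the oligos recovered DNA of the genes they come from. Inside MEG3 (chromosome 14, 100826108 to 100861026) there were 5 captured regions with MEG3 TFR1, 3 with MEG3 TFR2 and 5 with GATA6-AS TFR1, and 1 control region, which was in the GATA6-AS TFR1 comparison. The highest ratio in the gene was 9.27-fold with MEG3 TFR2 (100828651 to 100828900), and the highest with MEG3 TFR1 was 2.58-fold (100860051 to 100860300), below the 4.73-fold of GATA6-AS TFR1 (100852151 to 100852500). Within 100 kb of MEG3 there were 35 captured regions with GATA6-AS TFR1, 16 with MEG3 TFR1 and 14 with MEG3 TFR2. Per Mb these were 149, 68.1 and 59.6, against 39.5, 31.2 and 28.3 over chromosome 14. The higher density at MEG3 was thus not particular to the MEG3 oligos. The mean over chromosome 14 does not allow for position, and MEG3 lies within 10 Mb of the end of that chromosome. Over the autosomes, the share of captured regions this near an end exceeded the share of the span there for each oligo. How much of the higher density at MEG3 goes with its position near the end was not tested. Inside DLK1, the neighbouring paternally expressed gene (100726892 to 100738224), GATA6-AS TFR1 had 6 captured regions, up to 8.30-fold (100736351 to 100737000), MEG3 TFR2 had 1 and MEG3 TFR1 had 0. Inside GATA6-AS1 (chromosome 18, 22166898 to 22168968) GATA6-AS TFR1 had 1 captured region, at 2.05-fold (22167751 to 22168100), and the MEG3 oligos had 0. Inside GATA6 itself (22169589 to 22202528) MEG3 TFR1 had 1, at 6.75-fold (22170001 to 22170200), and MEG3 TFR2 and GATA6-AS TFR1 had 0. Within 100 kb of GATA6-AS1 there were 6 captured and 3 control regions with GATA6-AS TFR1, 7 and 3 with MEG3 TFR1, and 3 and 2 with MEG3 TFR2, and within 100 kb of GATA6 6 and 3, 12 and 3, and 5 and 2. Captured regions within 100 kb of GATA6-AS1 came to 29.7, 34.6 and 14.8 per Mb for GATA6-AS TFR1, MEG3 TFR1 and MEG3 TFR2. Over chromosome 18 the values were 16.6, 22.3 and 19.0. No test was made at these genes.

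**Figure D5:**
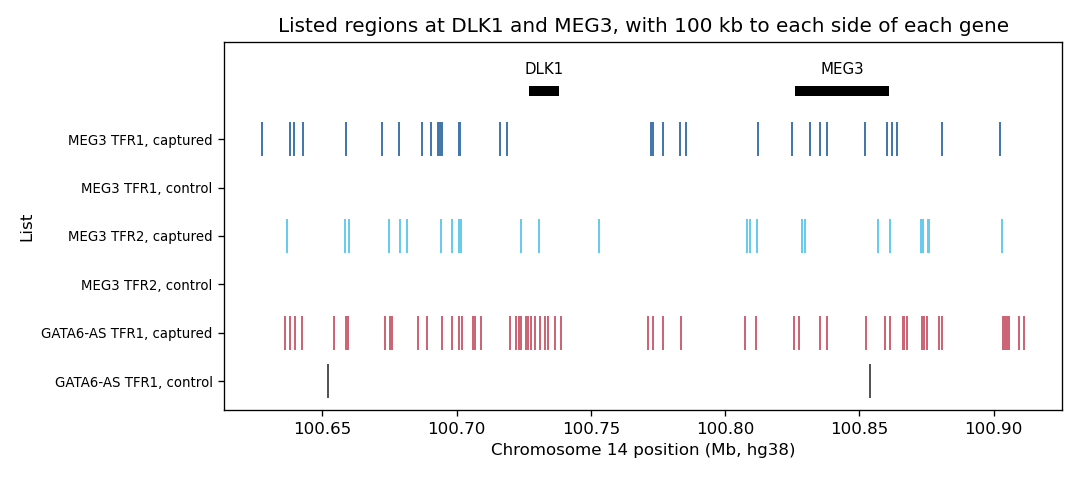
Positions of captured (coloured) and control (dark grey) regions on chromosome 14 (x axis, Mb on hg38) at DLK1 and MEG3 with 100 kb to each side, one row per list (y axis). GATA6-AS TFR1 had 6 captured regions inside DLK1, where MEG3 TFR2 had 1 and MEG3 TFR1 had 0.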

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

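The comparison with moved regions in this part was chosen after seeing the data. The differences below were each found by a test of the difference between 2 oligos' odds ratios, captured against control, with Benjamini-Hochberg adjustment over 12 tests, and the p-values are over regions that are not replicates. That test treats the 2 odds ratios as independent, although all comparisons share the no-oligo libraries and the control lists overlap. The groups of 2 libraries were too small for a search for outlying samples, and no values per library were at hand.

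The edges of protein-coding genes set the oligos apart most. The odds ratio of MEG3 TFR1 was 0.474 times, and that of MEG3 TFR2 0.388 times, that of GATA6-AS TFR1 (adjusted p 3.74e-30 and 5.92e-46). The MEG3 oligos also differed from each other, with a ratio of 1.22 for MEG3 TFR1 over MEG3 TFR2 (adjusted p 0.0181), where the captured shares were near each other over placed chance (1.95 and 1.87) and the control shares were 2.91% and 3.26%. DNA inside other genes went the other way, with odds ratios below 1 for all: 0.929 for MEG3 TFR1, 0.933 for MEG3 TFR2 and 0.745 for GATA6-AS TFR1. The odds ratio was 1.25 times that of GATA6-AS TFR1 for MEG3 TFR1 (adjusted p 6.39e-10) and for MEG3 TFR2 (adjusted p 2.04e-09). Against moved regions the MEG3 ratios were 1.02 and 0.999 (two-sided permutation p = 0.058 and 0.933). DNA between genes also went the other way, with ratios of 1.21 (adjusted p 2.23e-15) and 1.23 (adjusted p 1.15e-15). The GATA6-AS TFR1 control list, with 36330 regions, is the longest, and its share at gene edges, 2.66%, was the lowest of the 3 control lists.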

How the results depend on the processing

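Settings with moved regions, density strata, a log2 ratio of at least 1.5 or chromosome 1 left out were chosen after seeing the data, and the comparison of moved gene counts with other genes after the plain moved ratio had been seen. Of the recomputed values, 248 kept their direction and their side of the threshold or, where they were counts, stayed within 1.5 times. Another 42 turned direction (with or without a change of side), and 19 counts moved by over 1.5 times. Of those that kept their direction, 9 lost the threshold and 6 gained it. Overlap of captured lists stayed above chance in every setting (2.37 to 11.2 times), and the gene edge ratio stayed above 1, at 1.53 to 6.01 against the control lists and 1.26 to 1.97 against moved regions. No paired analysis was possible because the lists carry no value per library. For the same reason fits that leave a library out or block by experiment were not run, and depth could not be examined. Purine tract, 6-mer and GC settings, GC-matched placement, masking of repeats and tract-only overlap were not run, since no genome was used here.

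Keeping the 50% of regions with the largest log2 ratio left, by construction, 44869 captured and 6324 control regions for MEG3 TFR1, 36773 and 5472 for MEG3 TFR2, and 52393 and 18165 for GATA6-AS TFR1. A log2 ratio of at least 1.5 left 38025 and 6688, 32755 and 5076, and 36983 and 20200. Gene lists past the threshold, 1 for each oligo, became 2 with gene bodies (MEG3 TFR1, GATA6-AS TFR1; synaptic genes gained), 2 within density strata (MEG3 TFR1, synaptic genes gained; GATA6-AS TFR1, neuroectoderm genes gained), 2 with 5 kb edges (GATA6-AS TFR1, ribosomal genes gained) and, with moved regions against other genes, 0 for MEG3 TFR2 and 0 for GATA6-AS TFR1. For MEG3 TFR1 that count stayed at 1 but the list was synaptic genes (ratio 1.97, adjusted p 0.0360) and not HOX. With gene bodies the count for MEG3 TFR2 also stayed at 1, again synaptic genes and not HOX.

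The inside of protein-coding genes turned to below 1 with 5 kb edges, which take up part of it, for MEG3 TFR1 (0.978), MEG3 TFR2 (0.987) and GATA6-AS TFR1 (0.860), against moved regions (0.967, 0.996 and 0.978), and in the top 50% for MEG3 TFR2 (0.992). The 0.996 of MEG3 TFR2 against moved regions was not apart from 1 (two-sided permutation p = 0.148). Against moved regions the MEG3 TFR1 ratio was 1.02 inside other genes and 1.00 between genes.

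Odds ratios of gene lists turned as follows, none past the threshold except synaptic genes with GATA6-AS TFR1 over gene bodies. For MEG3 TFR1 they were TGF-beta and BMP in the top 50% (0.973), cardiac and imprinted over gene bodies (0.993 and 1.12), Polycomb within strata, without chromosome 1 and against moved regions (0.843, 0.965 and 0.887), ribosomal with 5 kb edges and without chromosome 1 (1.19 and 1.00), and synaptic with 5 kb edges (0.748). For MEG3 TFR2 they were TGF-beta and BMP over gene bodies (1.72), pluripotency in the top 50% and with 5 kb edges (0.979 and 0.684), neuroectoderm with 5 kb edges (1.56), imprinted in the top 50% (0.834), a list not described here in the top 50%, with 5 kb edges, over gene bodies, within strata and against moved regions (0.159, 0.856, 0.892, 0.936 and 0.981), ribosomal in the top 50%, over gene bodies, within strata and against moved regions (0.968, 0.634, 0.902 and 0.916), and synaptic with 5 kb edges (0.933). For GATA6-AS TFR1 they were Polycomb within strata and against moved regions (0.797 and 0.844), ribosomal in the top 50%, within strata and against moved regions (0.890, 0.920 and 0.832), and synaptic in the top 50%, over gene bodies, within strata and against moved regions (1.48, 9.04, 2.08 and 1.43). Except where the construction shows it, the cause was not tested.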

Other observations

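The gene families, the gene density relation and the chromosome patterns in this part were chosen after seeing results, the families after the HOX result and before their own values.

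Olfactory receptor genes were depleted with every oligo: 15 of 392 had a region with GATA6-AS TFR1, 30 with MEG3 TFR1 and 21 with MEG3 TFR2 (odds ratios 0.0436, 0.207 and 0.194; adjusted p 4.78e-82, 4.79e-23 and 3.35e-19). Against moved regions their ratios were 0.279, 0.690 and 0.637 (adjusted p 0.0011 each). Control regions were also few at olfactory receptor genes, at 9, 4 and 2 of the 392 in the same order. Of all protein-coding genes 5.92%, 2.33% and 2.22% had one. The shortage was thus not confined to captured DNA, and captured and control shares were not compared by a test. Histone genes were depleted with MEG3 TFR1 (1 of 74, odds ratio 0.0348, adjusted p 9.64e-09; moved ratio 0.131, adjusted p 0.0011), and with GATA6-AS TFR1 (11 of 74, odds ratio 0.197, adjusted p 6.12e-08) only in the first of these tests (moved ratio 0.879, adjusted p 0.491). With MEG3 TFR2 they stood at 8 of 74 (odds ratio 0.423, adjusted p 0.0436), but the moved ratio was 1.23 (adjusted p 0.485). Keratin genes were depleted with GATA6-AS TFR1 in both (38 of 149, odds ratio 0.386, adjusted p 6.21e-07; moved ratio 0.611, adjusted p 0.0011), and passed neither with MEG3 TFR1 (odds ratio 0.696, adjusted p 0.191) nor with MEG3 TFR2 (odds ratio 0.704, adjusted p 0.240). Protocadherin genes had a region at 31 of 65 with MEG3 TFR1 and 26 with MEG3 TFR2 (odds ratios 2.33 and 2.34, adjusted p 0.0034 and 0.0053; moved ratios 2.60 and 2.76, adjusted p 0.0011 each), but 37 of them share an end coordinate and only 11 and 9 distinct regions lay at their edges, so a single region counted for many genes. With GATA6-AS TFR1 28 had one (odds ratio 0.858, adjusted p 0.839; moved ratio 1.42, adjusted p 0.0193). Over the 14 families and 3 oligos, 42 tests, 16 passed the threshold, 11 passed against moved regions and 10 passed both, of which a part is described here. The families described were not picked to represent the others, and those left out that passed were not all depleted. Genes of a family lie together and are not independent.

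Captured regions per Mb rose with protein-coding genes per Mb over the 22 autosomes. Pearson's r was 0.959 for GATA6-AS TFR1, 0.940 for MEG3 TFR1 and 0.917 for MEG3 TFR2 (Spearman's rho 0.955, 0.949 and 0.931; adjusted permutation p 2e-05 each over 6 relations). Without chromosomes 19 and 17, the most gene-dense, r was 0.910, 0.923 and 0.881. For control regions r was 0.650, 0.508 and 0.572 (adjusted permutation p = 0.0012, 0.0240 and 0.0095) and rho 0.769, 0.689 and 0.723, and the difference from the captured regions was not tested. On chromosome X the captured lists reached 1.06% of their autosomal density. Among regions with a log2 ratio of at least 3 the value was 15.9% (95% interval 10.1% to 23.9%). Control regions were also nearly absent from X, with 3 for GATA6-AS TFR1, 0 for MEG3 TFR1 and 1 for MEG3 TFR2. The scarcity on X was thus seen in both kinds of list, and their densities there were not compared by a test.

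By counts over whole chromosomes, chromosome 1 had more captured regions per control region than its gene density gives. Residuals were taken from the line of log2 captured to control counts on gene density. That of chromosome 1 exceeded the highest of the other 21 autosomes by at least 0.42 in all 3 oligos. Gene density does not account for it in these counts. For GATA6-AS TFR1 it is left open, since neither arm exceeded the other chromosomes in bin medians that were also fitted on gene density. A copy change of one part of the chromosome was left open by a test of its arms. In medians of 10 Mb bins both arms exceeded all other chromosomes for the MEG3 oligos. For GATA6-AS TFR1 neither arm did (lowest margin -0.68). Counts over whole arms, a version run first, gave margins above 0 throughout (lowest 0.0616). The control density of chromosome 1 was the lowest of the 22 autosomes in each comparison (2.88 per Mb for MEG3 TFR1, 2.45 for MEG3 TFR2 and 9.02 for GATA6-AS TFR1). Its captured density, 45.8, 29.3 and 44.3 per Mb in the same order, was near that of chromosome 11, at 39.8, 32.6 and 46.6. Chromosome 11 has a like gene density, 9.65 against 9.12 genes per Mb, and control densities of 5.33, 4.69 and 14.6 per Mb. The pattern thus lies mainly in the control lists. A copy change in DNA common to oligo and no-oligo libraries would be expected to affect both lists. The shared no-oligo libraries make the 3 comparisons dependent. No biological explanation was tested.

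GATA6-AS TFR1 regions lay near chromosome ends more often than MEG3 regions: 30.5% were within 10 Mb of an end of the called span, against 23.1% for MEG3 TFR1 and 21.02% for MEG3 TFR2, where 14.3% of the span lies. Cutting the list to the MEG3 lengths left the share at 1.31 and 1.44 times theirs, so list length does not account for it. The share of the GATA6-AS TFR1 control list was at most 1.02 times those of the MEG3 control lists. That does not exclude regional background, since 76.1% and 80.9% of the MEG3 TFR1 and MEG3 TFR2 control regions overlapped that list. A bias of the GATA6-AS TFR1 libraries could also add captured regions near the ends without moving control regions there. Within strata of gene density the odds ratio was 1.37 against MEG3 TFR1 (95% interval 1.25 to 1.503) and 1.51 against MEG3 TFR2 (1.42 to 1.60), from crude values of 1.46 and 1.64, which leaves open that gene density could be part of it. The oligo sequence is the difference the design gives, and its role was not tested.

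The overlap of captured lists between oligos was above that of regions moved by 20 kb to 200 kb in each pair, at least 2.37 times, so regional density does not account for it. The shared no-oligo libraries could not be examined in the same way and may add to it. No biological explanation was tested.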
